A study of Mus musculus with 12 samples.

How the data were processed

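The series measured mouse R1 embryonic stem cells that carried a scrambled control or a Set knockdown, on a 1-colour Affymetrix gene array with 1 array per sample. The knockdown came as 2 lines, KD1 and KD2. Each line was sampled as growing stem cells (ESC; 15% serum and 1000 U/ml of leukemia inhibitory factor) and after 4 days in 1 µM retinoic acid with 10% serum and no such factor (RA). RA and ESC thus differ in retinoic acid, serum and this factor at once. A change between them cannot be credited to retinoic acid alone. The sampling gave 6 groups of 2 arrays, 12 arrays in all. Per the labels, biotinylated cRNA was made from 300 ng of total RNA.

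The authors deposited log2 values made by RMA, per the submitters' processing notes, with no version given: background correction, normalization between arrays and 1 value per probe set. The deposited table held 35556 probe sets. Genes came from the platform annotation, which listed 23410 of them; 21789 had 1 gene symbol, 1621 had several symbols, and 12146 were absent from it. The RefSeq table of assembly GRCm38.p6 served for current names, chromosomes and neighbours. A gene was represented by its brightest probe set with 1 symbol, which gave 19938 genes. Probe sets without a gene or with several were left out of the gene-wide tests. The probe sets of Set were tested apart, among the 23410 annotated ones, because the 2 bright ones are shared with BC085271.

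Array medians lay between 7.17 and 7.24 log2 units, and no array was dropped from the planned fit. The number of arrays limits precision, and with 2 arrays per group the spread was pooled over groups. Groups were set from the sample labels alone, and no array was moved to another group.

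Before the data were examined, the comparisons, tests, gene lists and alternatives were fixed. Limma version 3.58.1 in R 4.3.3 fitted the 6 groups to all 12 arrays, which left 6 residual degrees of freedom. Empirical Bayes moderation with an intensity trend added 2.76 prior degrees of freedom. The 5 main comparisons were KD against scrambled in ESC, KD against scrambled in RA, RA against ESC in scrambled cells, RA against ESC in knockdown cells, and the interaction. KD is the mean of the KD1 and KD2 groups. A further 6 comparisons took each line against scrambled and KD1 against KD2 in each state. P-values were adjusted by Benjamini-Hochberg over the 19938 genes, and a gene was called at an adjusted p below 0.05. The p-values measure the spread between arrays of the same lines, since each knockdown is 1 line and the scrambled control is another. Figures were drawn with matplotlib 3.10.9.

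Gene groups were 27 lists written from general knowledge: naive pluripotency, formative and primed pluripotency, retinoic acid response, Hox genes, neuroectoderm and neurons, mesoderm, endoderm and extraembryonic endoderm, trophoblast, two-cell-stage genes, SET partners and histone chaperones, p53 targets, S phase, G2 and M phase, ribosome biogenesis and Myc targets, Wnt targets, interferon response, fibroblasts and smooth muscle, epithelial junctions, mesenchymal transition, imprinted genes, Y-linked genes, germline methylation-dependent genes, polycomb subunits, replication-dependent and variant histones, hypoxia and glycolysis, cholesterol synthesis, and the integrated stress response. Each was tested with camera at a preset correlation between genes of 0.01, adjusted over the 27 lists. Each was also tested with a correlation estimated from the residuals and with fry. Members were counted as risen or fallen by the gene-wide call, and again with p-values adjusted over the list alone.

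Named genes followed a rule fixed with the design. Set came first. Each main comparison then took the 8 largest called changes each way (5 each way for the interaction and for KD1 against KD2). Predicted genes and RNA-class names were left out. So were genes whose higher group mean lay under 7.22, the median of all values, and genes whose arrays overlapped between the sides. Each list gave at most 4 called members, or its most changed member where none was called. A gene outside the rule is marked as chosen after its values were seen.

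The arrays labelled ESC KD2 replicate 2 and RA KD2 replicate 2 were found to resemble the other state. An alternative without these 2 arrays was therefore added after the data were seen. It left 10 arrays, 4 residual degrees of freedom and 4.93 prior ones. KD2 is then 1 array per state, which is assumed to vary like the other groups.

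The labels give replicate numbers but no shared day or batch. Replicate differences correlated within each state, from 0.141 to 0.633 over 6 pairs of groups, but from -0.864 to 0.105 over 9 pairs between states. The KD2 groups each hold an array that resembled the other state, and -0.864 is the value between them. For scrambled against KD1, the values within a state were 0.633 in ESC and 0.150 in RA. Between states, pairs of scrambled and KD1 groups lay from -0.0193 to 0.068. Comparisons within a state were therefore also fitted with a replicate block within each state, added after the data were seen. Its values stand beside main results where they change a call or move a count by over 1.5 times, and others stand with the alternatives. With 10 arrays this leaves 2 residual degrees of freedom.

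Alternative settings, fixed with the design, were: no intensity trend, robust moderation, only genes above the 40th percentile of brightness, the mean of probe sets, every probe set, quantile normalization once more, cyclic loess, median centring, only the groups compared, knockdown lines pooled, line as a random block, each line alone, the replicate number as a block, and leaving out each array in turn.

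The fit was tested on simulated data with 100 genes changed by 1 and 100 by 2 log2 units. In KD against scrambled in ESC it recovered 58 and 94 of them with 12 arrays, and 88 and 98 without the 2 arrays. In RA against ESC in scrambled cells it recovered 65 and 90, and 77 and 97. The number of false calls lay between 7 and 11. On simulated lists, camera called the list of shifted genes and did not call the list of unshifted genes. The simulated genes varied independently, with no replicate effect and no array resembling another state. The simulation therefore does not test camera, or the number of false calls, where genes are correlated.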

Results

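Set RNA was lower in the knockdown arrays than in the scrambled arrays of the same labelled state, by the 2 bright probe sets that cover Set together with BC085271. Probe set 10470893 read 12.93 and 12.71 log2 units in the scrambled ESC arrays. It read 12.13 and 11.94 in KD1, 12.15 in KD2 replicate 1 and 11.87 in the array labelled ESC KD2 replicate 2. In RA it read 12.27 and 12.29 in scrambled cells, 11.29 and 11.17 in KD1, 11.70 in KD2 replicate 1 and 11.99 in the array labelled RA KD2 replicate 2. Over 4 knockdown and 2 scrambled arrays per state, the signal fell to 57.6% of scrambled in ESC (log2 -0.80, SE 0.12, adjusted p = 0.0388) and to 59.5% in RA (log2 -0.75, SE 0.12, adjusted p = 0.0285). Probe set 10587486 gave -0.82 (SE 0.15, adjusted p = 0.109) and -0.68 (SE 0.15, adjusted p = 0.0919), which did not pass. KD1 in RA fell to 48.1% by probe set 10470893 (adjusted p = 0.00773), while KD2 in RA stood at 73.7% (adjusted p = 0.298) and was not called. The 2 dimmer probe sets annotated to Set alone were not called for the knockdown. Probe set 10470905 gave -0.74 (SE 0.43, adjusted p = 0.858) in ESC and 0.44 (adjusted p = 0.703) in RA; probe set 10470907 gave -0.38 (adjusted p = 0.877) and 0.45 (adjusted p = 0.585). In scrambled cells probe sets 10470893 (-0.54, adjusted p = 0.0448), 10587486 (-0.66, adjusted p = 0.0452) and 10470905 (-2.04, adjusted p = 0.043) were lower in RA than in ESC.

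**Figure D1:**
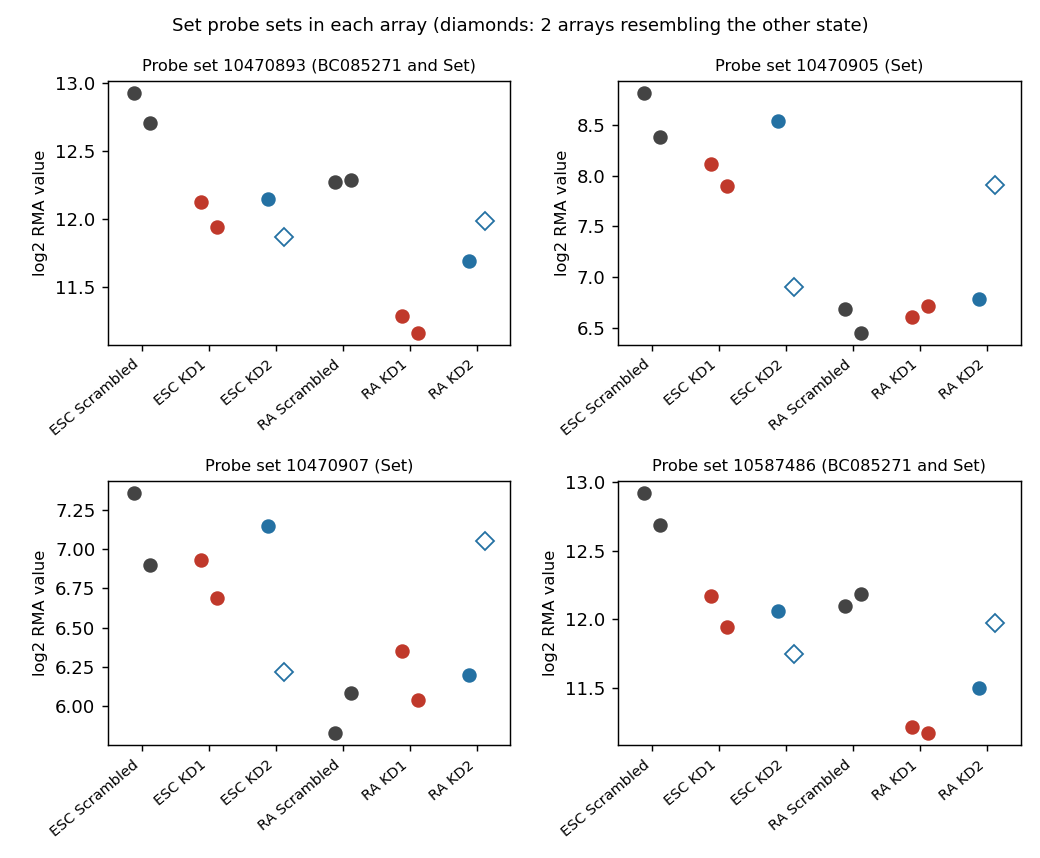
Values of the 4 Set probe sets in each array. Diamonds mark the 2 displaced arrays, under their labels.

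The array labelled ESC KD2 replicate 2 and the array labelled RA KD2 replicate 2 each resembled the other state. The first had a mean correlation of 0.952 with the other ESC-labelled arrays and 0.991 with RA-labelled ones, and its best match was RA KD2 replicate 1 (0.998). The second had 0.952 with RA-labelled and 0.991 with ESC-labelled arrays, and its best match was ESC Scrambled replicate 2 (0.994). Naive, Hox, retinoic acid and endoderm genes moved with this displacement, so KD means over all 12 arrays mix the states. Each comparison below therefore gives the planned fit of 12 arrays first and then the fit without these 2 arrays, which was added after the data were seen. In that fit, Set by probe set 10470893 fell by 0.73 in ESC and by 0.82 in RA, and by probe set 10587486 by 0.75 and 0.80. The probe sets annotated to Set alone gave -0.33 in ESC and 0.16 in RA (10470905), and -0.15 and 0.24 (10470907).

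**Figure D2:**
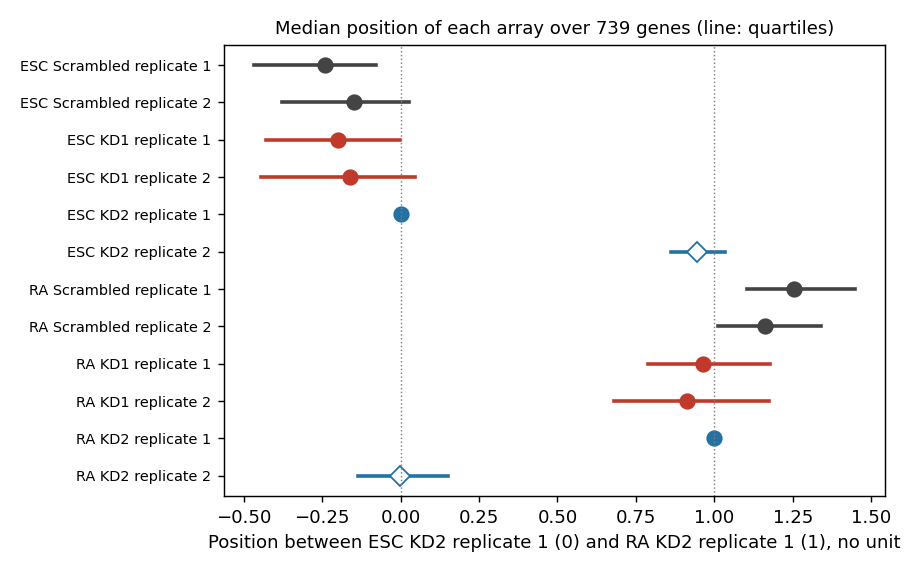
Median position and quartiles of each array over 739 genes between ESC KD2 replicate 1 (0) and RA KD2 replicate 1 (1). Diamonds mark the 2 displaced arrays.

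In ESC, the Y-linked genes Zfy1 and Kdm5d and the germline gene Asz1 were lower in the knockdown lines than in the scrambled line. Each knockdown is 1 line, so line and knockdown cannot be told apart. Zfy1 fell by 3.68 (SE 0.49), Dnajc5g by 2.79 (SE 0.30), Efhc2 by 2.49 (SE 0.23) and Kdm5d by 1.86 on the log2 scale (SE 0.10, adjusted p = 0.000539), with 4 knockdown and 2 scrambled arrays. Ct55 (-1.80), Nxf3 (-1.80), Ddr2 (-1.78), Asz1 (-1.70) and Rhox1 (-1.38) also fell. In all, 19 genes fell and 0 rose by limma, with 1296 of 19938 genes at an unadjusted p below 0.05. With a replicate block within each state, 7 fell and 0 rose (1781 at an unadjusted p below 0.05), and Zfy1 (adjusted p = 0.0635), Efhc2 (adjusted p = 0.0575), Ddr2 (adjusted p = 0.0588) and Rhox1 (adjusted p = 0.0608) were not called. Single arrays moved the 19 as well: 3 fell without ESC Scrambled replicate 2, 4 without KD1 replicate 1, 5 without KD1 replicate 2, 12 without KD2 replicate 1 and 10 without ESC KD2 replicate 2.

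Among gene groups in ESC, 2 of 7 Y-linked genes fell, Zfy1 and Kdm5d (3 adjusted over the list alone), and camera placed the list lower (adjusted p = 2.96e-07; adjusted p = 0.0288 with an estimated correlation, and 0.188 with that and the block within each state). Of 22 germline methylation-dependent genes, Asz1 fell (1 adjusted over the list alone); camera placed the list lower (adjusted p = 2.97e-05; adjusted p = 0.0584 with an estimated correlation). The endoderm list was placed higher with 0 of 33 members called and 29 above 0 (adjusted p = 1.51e-06; adjusted p = 0.638 with an estimated correlation). Its most changed member, Srgn, stood at 2.64 (SE 0.65, adjusted p = 0.396). Trophoblast genes were placed higher, with 0 of 21 called (adjusted p = 6.59e-05; adjusted p = 0.344 with an estimated correlation), and S-phase genes lower, with 0 of 28 called (adjusted p = 0.00139; adjusted p = 0.716 with an estimated correlation). Naive pluripotency genes were placed lower with 0 of 30 called (adjusted p = 0.00913; adjusted p = 0.716 with an estimated correlation), Dppa3 being the most changed at -2.11 (SE 0.94, adjusted p = 0.771). Of the 27 lists, camera placed 8 higher and 8 lower, and 1 call was kept with an estimated correlation.

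With the 2 displaced arrays left out, 107 genes rose and 100 fell in ESC, among them all 19 of the genes that fell in the planned fit. The block within each state gave 688 and 536 in this fit, including all 207. The counts were 173 and 252 without ESC Scrambled replicate 1, 70 and 58 without replicate 2, and 35 and 49 without KD1 replicate 1. Endoderm genes rose: Srgn by 2.10 (SE 0.34), Cubn by 1.73 (SE 0.13, adjusted p = 0.000822), Gata6 by 1.34 (SE 0.10, adjusted p = 0.00092) and Dab2 by 1.12 (SE 0.10, adjusted p = 0.00251). Calml4 (1.70), Apobec2 (1.65), Cntfr (1.56), Glipr1 (1.25) and Ptges (1.24) also rose. Calb2 (-1.80), the imprinted gene Grb10 (-1.45, SE 0.15), the naive gene Dppa3 (-1.32, SE 0.17) and Uba1y (-1.22, SE 0.21) fell. Of 33 endoderm genes 6 rose and 0 fell (15 and 1 adjusted over the list alone), with camera at adjusted p = 4.44e-11 and adjusted p = 0.053 with an estimated correlation. Of 22 germline genes 3 fell, Asz1 (-1.65) and Rpl10l (-0.94) among them, with 6 adjusted over the list alone; camera gave adjusted p = 4e-06, and adjusted p = 0.0965 with an estimated correlation. Of 21 trophoblast genes 3 rose, Krt8 (0.71), Tead4 (0.65) and Peg10 (0.28), and 11 adjusted over the list alone (camera adjusted p = 4e-06; adjusted p = 0.131 with an estimated correlation). The trophoblast median was -0.01 in KD1 and 0.62 in KD2, so the shift came from the single KD2 array. The endoderm median in KD1 was 0.22. On the axis from ESC KD2 replicate 1 (0) to RA KD2 replicate 1 (1), the scrambled and KD1 ESC arrays lay between -0.240 and -0.147. The single KD2 array thus lay nearer to RA than they did. Whether this shift raised endoderm genes in its ESC values was not tested. In the two-cell-stage list 0 of 11 members passed and 6 fell adjusted over the list alone (camera adjusted p = 5.93e-05; adjusted p = 0.182 with an estimated correlation). Of 30 naive genes, Dppa3 alone was called, and the list was not (camera adjusted p = 0.336). Bmp4 (0.78) and Sp5 (0.75) rose and Lef1 (-0.60) fell among 22 Wnt targets; Xaf1 (0.73) and Oas2 (0.68) rose among 25 interferon genes; Perp (0.75) rose among 28 p53 targets. The lists of SET partners and histone chaperones (30 members), polycomb subunits (23) and histones (17) had 0 called members and no camera call in either fit in ESC.

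In RA, the imprinted gene Grb10 and 5 of 37 Hox genes were lower in the knockdown lines in the planned fit. In that fit 5 of 24 hypoxia and glycolysis genes were higher. Its KD2 group holds the array labelled RA KD2 replicate 2, which resembled ESC. Without the 2 displaced arrays the Hox median was -0.63 in KD1 and -0.26 in KD2, with 4 and 13 members above 0. The hypoxia and glycolysis median was then 0.49 in KD1 and 0.385 in KD2. The values that follow are of the planned fit. Grb10 (log2 -3.44, SE 0.26, adjusted p = 0.00149) and Hoxb13 (-3.20, SE 0.39) fell, while Pga5 rose by 2.75 (SE 0.39) and Htra1 by 2.32 (SE 0.22, adjusted p = 0.0038), with 4 knockdown and 2 scrambled arrays. Laptm5 (2.57), Serpinb6c (2.37), Epas1 (2.24), Ptk6 (2.22), Aqp8 (2.16) and Flt1 (2.04) also rose. Igfbp7 (-2.47), Sst (-2.22), Matn2 (-2.16), Mamdc2 (-2.07), Isl1 (-2.03) and Angpt2 (-2.02) fell. In all, 106 genes rose and 121 fell. Kdm5d fell in RA as well (-1.93, SE 0.10, adjusted p = 0.000233), and 6 of the 19 genes lowered in ESC were also lowered in RA, against 0.115 expected of independent lists. The lists are not independent, since both states compare the same lines and a difference between lines would recur in both. With the block within each state, 103 rose and 120 fell, and Laptm5 (adjusted p = 0.0594) and Aqp8 (adjusted p = 0.0529) were not called. Without RA Scrambled replicate 1 the counts were 3 and 10, without replicate 2 8 and 25, without KD1 replicate 1 27 and 33, without KD1 replicate 2 19 and 19, without KD2 replicate 1 205 and 372, and without RA KD2 replicate 2 96 and 77.

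Of 37 Hox genes 5 fell and 0 rose (9 adjusted over the list alone), among them Hoxb13, Hoxd1 (-0.94), Hoxd11 (-0.84) and Hoxd10 (-0.79). Camera placed the Hox list lower (adjusted p = 5.19e-11; adjusted p = 0.587 with an estimated correlation). Of 24 retinoic acid response genes Lrat fell (-1.09, SE 0.16), with camera lower at adjusted p = 0.0038 and adjusted p = 0.587 with an estimated correlation. Hnf4a (1.33, SE 0.23) and Lamc1 (1.13, SE 0.21) rose among 33 endoderm genes, and 11 rose and 2 fell adjusted over the list alone. Camera placed the endoderm list higher (adjusted p = 0.000127; adjusted p = 0.587 with an estimated correlation). Of 24 hypoxia and glycolysis genes 5 rose, including Pfkl (1.70), Slc2a3 (1.22), Ldha (0.76) and Aldoa (0.59), and 12 adjusted over the list alone (camera adjusted p = 1.4e-08; adjusted p = 0.587 with an estimated correlation). In the G2 and M list 0 of 29 genes passed and 18 rose adjusted over the list alone (camera adjusted p = 5.82e-13; adjusted p = 0.587 with an estimated correlation). Lin28a rose among 30 naive genes (1.17, SE 0.18), Tead4 among 21 trophoblast genes (0.86) and Insig1 among 19 cholesterol genes (1.42, SE 0.14). Ifit2 (-1.39) and Ifit1 (-0.53) fell among 25 interferon genes. Of the 27 lists camera placed 8 higher and 6 lower, and 0 calls were kept with an estimated correlation. With the block within each state, Lrat (adjusted p = 0.0504), Hoxd1 (adjusted p = 0.0505), Lamc1 (adjusted p = 0.0686), Tead4 (adjusted p = 0.0727), Ifit2 (adjusted p = 0.0509), Pfkl (adjusted p = 0.0509) and Aldoa (adjusted p = 0.065) were not called.

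In the fit of 10 arrays, 532 genes rose and 674 fell in RA, including all 106 and 121 genes of the planned fit, and 1427 and 1886 with the block within each state. Without RA Scrambled replicate 1 they were 205 and 237, without replicate 2 265 and 352, without KD1 replicate 1 274 and 397, and without KD1 replicate 2 249 and 308. Endoderm genes rose: Cubn by 3.35 (SE 0.13, adjusted p = 7.72e-06), Srgn by 2.80, Lama1 by 2.74 (SE 0.10), Sox7 by 2.12 (SE 0.14). Pga5 (2.80), Klb (2.69), Glipr1 (2.60), Nostrin (2.58), Ptk6 (2.34) and Pdgfra (2.02) rose as well. Grb10 (-3.21, SE 0.15), Hoxb13 (-2.88, SE 0.15), Cxcl15 (-2.53), Tbx18 (-2.29) and Edil3 (-1.95) fell. Of 33 endoderm genes 19 rose and 2 fell (21 and 2 adjusted over the list alone), with camera at adjusted p = 1.48e-15 and adjusted p = 0.0381 with an estimated correlation (0.184 with that and the block within each state). The list's median stood at 1.87 in KD1 and 0.41 in KD2, and 22 members rose in KD1 alone and 3 in KD2 alone. Of 37 Hox genes 13 fell and 0 rose, with Hoxd8 (-1.21) and Hoxb9 (-0.99) besides Hoxb13 (18 and 2 adjusted over the list alone; camera adjusted p = 1.93e-10; adjusted p = 0.16 with an estimated correlation). In KD1 alone 21 Hox genes fell, and in KD2 alone 1 fell and 1 rose. Of 29 G2 and M genes 11 rose, among them Anln (0.45), Kif23 (0.43), Birc5 (0.42) and Aurka (0.42), and 23 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.87e-11; adjusted p = 0.0817 with an estimated correlation). Of 24 hypoxia and glycolysis genes 10 rose and 1 fell (11 and 2 adjusted over the list alone), with Egln3 (1.75), P4ha2 (1.67), P4ha1 (1.45) and Pfkl (1.42) in front (camera adjusted p = 1.99e-08; adjusted p = 0.468 with an estimated correlation). Of 30 naive genes 7 rose, including Lin28a (1.11), Fbxo15 (1.06), L1td1 (0.99) and Klf4 (0.89). The lines differed, with a naive median of -0.23 in KD1, where 8 rose and 5 fell, and of 0.45 in KD2, where 2 rose and 0 fell. Camera gave the naive list adjusted p = 0.0612, and 0.0141 with the block within each state (adjusted p = 0.775 with the block and an estimated correlation). Retinoic acid response genes split: Cyp26b1 (-1.01), Dhrs3 (-0.90) and Lrat (-1.07) fell and Cyp26a1 rose (0.82, SE 0.17, adjusted p = 0.0256), with 2 of 24 up and 3 down. Of 26 imprinted genes 5 fell, Grb10, Zim1 (-1.13), Plagl1 (-0.92) and Dcn (-0.89) among them, with camera at adjusted p = 0.000124 and adjusted p = 0.0817 with an estimated correlation. Mesoderm genes split, with Pdgfra and Snai1 (0.97) up and Foxc2 (-1.50) and Tbx5 (-0.93) down. Postn (-1.25) and Col3a1 (-0.76) fell among 24 fibroblast genes, and Cdh11 (-1.53), Tgfb2 (-1.06) and Snai2 (-0.98) among 22 mesenchymal genes.

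**Figure D3:**
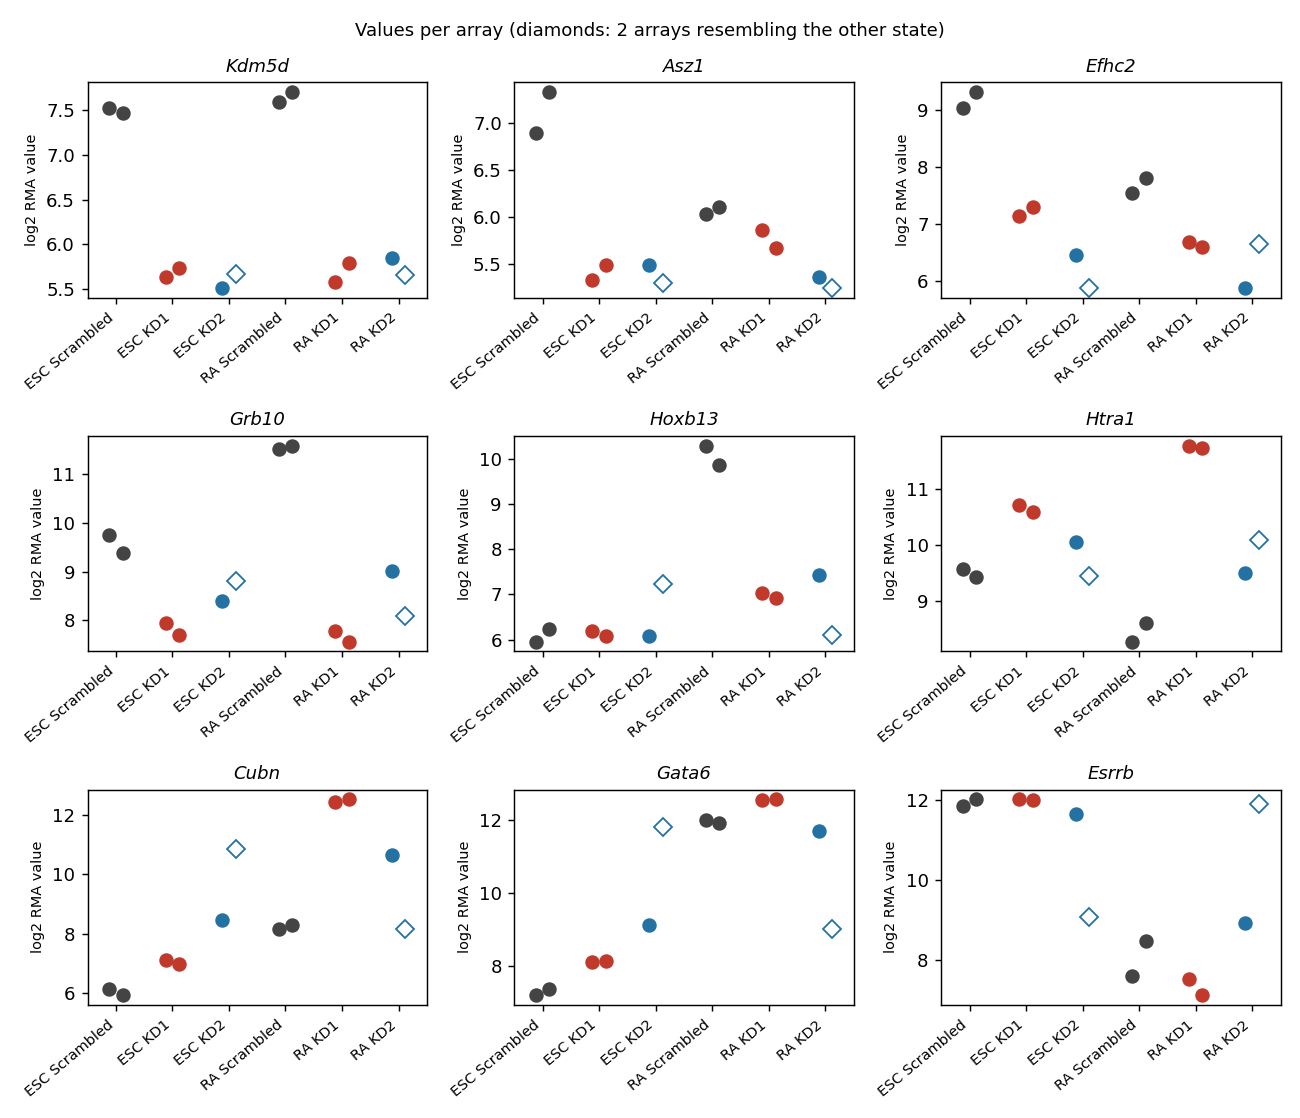
Values of 9 named genes in each array. Diamonds mark the 2 displaced arrays, under their labels.

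In scrambled cells, some mesenchymal, endoderm and Hox genes were higher in RA than in ESC, and many naive pluripotency genes were lower. Retinoic acid, serum and leukemia inhibitory factor all differed between the states, so their shares cannot be told apart. Camera placed 9 lists higher and 8 lower in the planned fit, and 0 calls were kept with an estimated correlation. Nrp1 rose by 5.37 (SE 1.53, 41.4-fold), Dcn by 5.19 (SE 1.18) and Plat by 4.84 (SE 1.19), while Tcl1 (-4.72, SE 1.32), Nr0b1 (-4.17, SE 1.07) and Esrrb (-3.91, SE 0.98) fell, with 2 arrays per group. Slc16a12 (5.36), Cdh11 (5.22), Ecm1 (5.12), Edil3 (5.03) and P4ha3 (4.98) also rose. Tdgf1 (-3.98), Pipox (-3.86), Zfp42 (-3.85), Pfkp (-3.77) and Stmn2 (-3.69) also fell. In all 1622 genes rose and 1129 fell. Without ESC Scrambled replicate 1 the counts were 19 and 10, without ESC Scrambled replicate 2 3 and 0, without RA Scrambled replicate 1 10 and 0, and without RA Scrambled replicate 2 54 and 7. Without the 2 displaced arrays the scrambled means were the same and the pooled spread shrank: 4342 genes rose and 4154 fell, and Meis2 (5.40, SE 0.25), Rarb (5.37, SE 0.16), Nr2f2 (5.33) and Hoxa5 (5.17) were then called.

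Of 30 naive genes 18 fell and 0 rose (28 adjusted over the list alone; camera adjusted p = 2.53e-10; adjusted p = 0.389 with an estimated correlation). Of 18 formative and primed genes 5 fell, Zic5 (-3.26), Etv5 (-2.95), Dnmt3b (-2.31) and Nodal (-2.12) among them (camera adjusted p = 0.0914). Of 24 retinoic acid response genes 5 rose, including Dhrs3 (4.75), Cyp26b1 (3.28), Tgm2 (2.64) and Pbx3 (1.37), with 16 up and 1 down adjusted over the list alone (camera adjusted p = 5.44e-06; adjusted p = 0.389 with an estimated correlation). Of 37 Hox genes 12 rose, among them Hoxb13 (3.98, SE 0.45), Hoxa3 (3.15), Hoxb9 (2.98) and Hoxd8 (2.00), and 27 adjusted over the list alone (camera adjusted p = 2.8e-10; adjusted p = 0.389 with an estimated correlation). Of 33 endoderm genes 9 rose and 1 fell, with Gata6 (4.67), Dab2 (3.99) and Foxa1 (3.51) besides Plat (14 and 2 adjusted over the list alone; camera adjusted p = 5.77e-05; adjusted p = 0.402 with an estimated correlation). Of 27 mesoderm genes 7 rose, including Foxc2 (4.53), Foxf1 (4.14), Twist1 (3.05) and Msx2 (2.30) (camera adjusted p = 0.0234; adjusted p = 0.389 with an estimated correlation). Of 21 trophoblast genes 9 rose, Gata3 (4.10), Gata2 (2.87) and Plac1 (2.63) in front (camera adjusted p = 7.74e-05; adjusted p = 0.389 with an estimated correlation). Of 35 neural genes 4 rose and 2 fell, with Isl1 (3.05) and Sox11 (2.33) up and Stmn2 down (camera adjusted p = 0.866).

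Some fibroblast, smooth muscle and mesenchymal transition genes were higher in RA than in ESC in scrambled cells. Of 24 fibroblast and smooth muscle genes 10 rose, including Acta2 (2.91), Tagln (2.87) and Cnn1 (2.72), and of 22 mesenchymal transition genes 9 rose, including Tgfb2 (4.35) and Zeb2 (3.32). Camera placed these lists higher (adjusted p = 1.13e-06 and 1.19e-06; for each, adjusted p = 0.389 with an estimated correlation). Of 26 imprinted genes 11 rose, with Airn (3.86), Zim1 (3.74) and Plagl1 (3.70) besides Dcn (camera adjusted p = 1.22e-07; adjusted p = 0.389 with an estimated correlation). Of 21 epithelial junction genes 4 rose, Krt18 (1.98), Krt8 (1.75), Dsp (1.58) and Prss8 (1.23) (camera adjusted p = 0.239). Of 28 p53 targets 4 rose and 1 fell, led by Perp (1.54) and Plk2 (1.47) (camera adjusted p = 0.0431; adjusted p = 0.483 with an estimated correlation). Of 22 Wnt targets 4 rose and 1 fell, Dkk1 (1.99) and Fzd7 (1.30) up and Notum (-1.56) down (camera adjusted p = 0.111). Of 25 interferon genes 6 rose, Usp18 (2.17) and Ifit2 (1.77) among them (camera adjusted p = 0.425).

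Most S-phase and G2 and M genes were lower in RA than in ESC in scrambled cells, as were some ribosome biogenesis, glycolysis and cholesterol genes. In the planned fit their list calls were lost with an estimated correlation. Of 28 S-phase genes 19 fell, with Hells (-1.74), Mcm10 (-1.59) and Pola1 (-1.37), and of 29 G2 and M genes 25 fell, with Hmmr (-1.18), Cenpf (-1.12) and Aurka (-1.06). Adjusted over the list alone, 25 and 29 fell. Camera gave adjusted p = 1.76e-10 and 3.66e-13 (for each, adjusted p = 0.389 with an estimated correlation). Of 31 ribosome biogenesis genes 9 fell, such as Dkc1 (-1.30) and Tcof1 (-1.22), and 26 adjusted over the list alone (camera adjusted p = 3.56e-09; adjusted p = 0.389 with an estimated correlation). Of 24 hypoxia and glycolysis genes 12 fell and 1 rose, with Egln3 (-2.96), Aldoc (-2.32) and Pfkl (-1.86) besides Pfkp (camera adjusted p = 8.37e-05; adjusted p = 0.389 with an estimated correlation). Of 19 cholesterol genes 4 fell, Idi1 (-1.52) and Lss (-1.03) first (camera adjusted p = 0.00118; adjusted p = 0.389 with an estimated correlation). Of 27 stress response genes 5 fell, Psat1 (-1.46) and Asns (-1.21) among them (camera adjusted p = 0.0032; adjusted p = 0.389 with an estimated correlation). Of 22 germline genes 5 fell, with Hormad1 (-2.10) and Rpl10l (-1.98) after Zfp42 (camera adjusted p = 0.0207; adjusted p = 0.389 with an estimated correlation). Of 30 SET partners and histone chaperones, Chaf1b (-0.91) and Nasp (-0.86) fell and Ppp2cb (0.40) rose (camera adjusted p = 0.153). Of 23 polycomb subunits Yaf2 (2.16) and Cbx8 (1.79) rose and Mtf2 (-0.96) fell (camera adjusted p = 0.98), and of 17 histone genes 1 rose, Macroh2a2 (1.64), and 4 fell, Cenpa (-0.78) first (camera adjusted p = 0.351). Zfy1 fell (-2.59) among 7 Y-linked genes (camera adjusted p = 0.322), and 0 of 11 two-cell-stage genes passed (camera adjusted p = 0.98). Without the 2 displaced arrays 4 of the 17 camera calls were kept with an estimated correlation: retinoic acid response (adjusted p = 0.0228), endoderm (0.0419), G2 and M (0.0419) and imprinted genes (0.0228).

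In knockdown cells, 100 genes were higher and 5 lower in RA than in ESC in the planned fit. There, each KD2 group holds arrays of differing resemblance. Without ESC KD2 replicate 2 the counts were 1702 and 1569, without RA KD2 replicate 2 1742 and 1017, and without any other single array between 2 and 35 higher and between 0 and 2 lower. Fgfr4 rose by 1.28 (SE 0.15, adjusted p = 0.0137), Cxcl10 by 0.96 (SE 0.16), Slc26a2 by 0.87 (SE 0.14) and Lif by 0.80 (SE 0.13), with 4 arrays per side. Tmem130 (0.71) and Phactr1 (0.52) rose too, as did Thbd (1.71), Snai1 (1.20) and the imprinted gene Zim1 (2.15). The 5 genes that fell were Atp2a3 (-1.28), Aqp3 (-1.14), Fam178b (-1.02), Spata31d1a (-0.89) and Il17rd (-0.66), chosen after their values were seen. Of 30 naive genes 0 passed and 14 fell adjusted over the list alone (camera adjusted p = 8.19e-10; adjusted p = 0.448 with an estimated correlation). Thbd rose among 33 endoderm genes, and 22 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.96e-13; adjusted p = 0.448 with an estimated correlation). In the S-phase list 0 of 28 members passed and 24 fell adjusted over the list alone (camera adjusted p = 2.69e-11; adjusted p = 0.448 with an estimated correlation). Camera placed 9 lists higher and 7 lower, and 0 calls were kept with an estimated correlation.

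Once the 2 displaced arrays were left out, many genes differed between RA and ESC in knockdown cells, KD2 then having 1 array per state. Cyp26a1 rose by 5.21 (SE 0.16, 36.9-fold), Rarb by 4.81 (SE 0.13), Meis2 by 4.65 (SE 0.22) and Ecm1 by 4.60 (SE 0.16), and Nrp1 (4.56), Nr2f2 (4.54), Meis1 (4.47) and Igfbp5 (4.45) followed. Trh (-4.99, SE 0.14), Glod5 (-4.29), Platr8 (-4.27), Nr0b1 (-4.22, SE 0.29), Calml4 (-4.22), Epp13 (-4.10), Liph (-4.08) and Septin1 (-4.07) fell. Of the genes that rose in scrambled cells 3480 also rose in knockdown cells, against 927 expected of independent lists, and 3182 of the falls were shared against 825. Of 30 naive genes 29 fell, with Tdgf1 (-3.99), Tcl1 (-3.79) and Esrrb (-3.73) (camera adjusted p = 6.68e-16; adjusted p = 0.163 with an estimated correlation). Of 33 endoderm genes 25 rose and 1 fell, with Plat (4.21), Cubn (3.80), Gata6 (3.50) and Dab2 (3.19) (camera adjusted p = 5.54e-15; adjusted p = 0.0195 with an estimated correlation). Of 24 retinoic acid response genes 19 rose and 1 fell, and of 37 Hox genes 26 rose, led by Hoxa5 (4.44) and Hoxc5 (4.28). Camera gave adjusted p = 1.56e-11 for the first (adjusted p = 0.0195 with an estimated correlation) and 4.26e-11 for the second (adjusted p = 0.125 with an estimated correlation). Of 28 S-phase genes 23 fell, led by Ung (-1.55) and Hells (-1.46), and of 31 ribosome biogenesis genes 30 fell, led by Dkc1 (-1.35) and Rrp9 (-1.35). Camera gave adjusted p = 1.25e-09 (adjusted p = 0.342 with an estimated correlation) and 2.17e-11 (adjusted p = 0.29 with an estimated correlation). Pdgfra (3.84), Foxf1 (3.26) and Osr1 (3.17) rose among 27 mesoderm genes, and Dlk1 (3.64) and Airn (3.08) among 26 imprinted genes. Grhl2 (-2.56), Esrp1 (-1.95) and Epcam (-1.48) fell and Krt18 (1.47) rose among 21 epithelial junction genes.

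The knockdown effect differed between the states at 6 genes in the planned fit, 1 higher and 5 lower in RA. Mamdc2 had the lower response in RA by 2.29 (SE 0.27, adjusted p = 0.0497). Lrrc7 (-1.87, SE 0.17), Pnliprp1 (-1.58), Kcnj2 (-1.56) and Sntg1 (-1.31) were lower and Lrpap1 (1.01, SE 0.12) higher, chosen after their values were seen. With the block within each state 0 genes were called by limma (2714 at an unadjusted p below 0.05), Mamdc2 then having an adjusted p = 0.0682. Leaving out 1 array gave 0 to 24 higher and 0 to 49 lower, the most without RA KD2 replicate 1. Camera placed Hox genes lower with 0 of 37 called and 5 adjusted over the list alone (adjusted p = 4.35e-10; adjusted p = 0.409 with an estimated correlation). It placed hypoxia and glycolysis genes higher with 0 of 24 called, and 9 higher and 1 lower adjusted over the list alone (adjusted p = 4.62e-08; adjusted p = 0.409 with an estimated correlation).

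The interaction called 140 genes higher and 236 lower in RA in the fit of 10 arrays, and 640 and 1077 with the block within each state. Leaving out 1 array gave between 41 and 267 higher and between 74 and 283 lower, the fewest without RA Scrambled replicate 1 and the most without ESC Scrambled replicate 1. Pga5 (3.22, SE 0.47), Serpinb6c (2.69, SE 0.29), Car8 (2.44, SE 0.29), Ptk6 (2.27, SE 0.16) and Nostrin (2.27, SE 0.27) responded more highly in RA. Hoxb13 (-2.90, SE 0.21), Igfbp7 (-2.60, SE 0.37), Tnfsf9 (-2.55, SE 0.31), Cxcl15 (-2.46, SE 0.24) and Tbx18 (-2.42, SE 0.25) responded lower. Of 33 endoderm genes 10 were higher and 4 lower, with Lama1 (2.07), Hnf4a (1.72) and Cubn (1.62) against Cxcl12 (-1.72) (camera adjusted p = 3.34e-06; adjusted p = 0.0871 with an estimated correlation). Of 26 imprinted genes 6 were lower, Grb10 (-1.77), Dcn (-1.36) and Nnat (-1.02) among them (camera adjusted p = 6.69e-08; adjusted p = 0.0801 with an estimated correlation). Of 24 hypoxia and glycolysis genes 4 were higher, P4ha2 (1.89), Pfkl (1.44), Ldha (0.77) and Aldoa (0.54) (camera adjusted p = 2.67e-10; adjusted p = 0.247 with an estimated correlation). Zfy1 (2.24) and Asz1 (1.15) were higher in the interaction, their fall in ESC being the larger.

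Some genes were called in both lines. In the planned fit KD1 raised 4 and lowered 9 genes in ESC and raised 315 and lowered 148 in RA. KD2 raised 2 and lowered 15 in ESC and raised 5 and lowered 49 in RA. Leaving out 1 array moved most of these counts widely, as given with the alternatives. With the block within each state KD1 raised 1 and lowered 2 genes in ESC, and KD2 raised 0 by limma (2785 either way at an unadjusted p below 0.05) and lowered 2. In ESC 8 genes were lower in both lines, and in RA 35 were lower and 3 higher. Over all genes the KD1 and KD2 changes correlated at 0.206 in ESC and 0.438 in RA, where simulated lines sharing only the scrambled arrays gave 0.507 and 0.492. The covariances were 0.0241 and 0.0797, against 0.0443 and 0.0424 simulated. In the fit of 10 arrays the correlations were 0.327 and 0.531 (simulated 0.416 and 0.412) and the covariances 0.0251 and 0.0582 (simulated 0.0137 and 0.0134). The scrambled arrays are the same in both fits, but the pooled spread was larger with the displaced arrays. The simulated values of 12 arrays therefore cannot show that the lines agreed less than shared controls alone would give. In that fit 13 genes were higher and 36 lower in both lines in ESC, and 36 and 108 in RA. KD1 had 383 calls in ESC and 2407 in RA in it, and KD2 197 and 192; with the block within each state these were 2098, 4786, 840 and 1007. With 1 scrambled array set against each line, no control array was shared. The correlations in the fit of 10 arrays were then -0.0143 and 0.103 in ESC and 0.407 and 0.38 in RA. With all 12 arrays they were 0.0712 and -0.0209 in ESC and 0.407 and 0.313 in RA. The scrambled arrays are of 1 line, so traits of that line still enter the changes of both knockdown lines. Replicate differences correlated within a state, and these pairings do not account for that.

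KD1 and KD2 differed at 26 genes in ESC and 268 in RA, counts that leaving out 1 array moved widely, in ESC to 0 each time. With the block within each state they differed at 0 in ESC by limma (4229 at an unadjusted p below 0.05) and 305 in RA, where Nostrin (adjusted p = 0.0513), Lefty1 (adjusted p = 0.0631) and Aqp3 (adjusted p = 0.0527) were not called. In ESC Serpinb6c (2.35, SE 0.33), Atp2a3 (2.14, SE 0.21) and Slc13a5 (2.04, SE 0.28) were higher in KD1, and Ghr (-2.08, SE 0.24), Krt18 (-2.03, SE 0.29) and Thbs1 (-1.84, SE 0.26) lower, with 2 arrays per line. In RA Ptk6 (3.61, SE 0.26), Klb (3.50, SE 0.53), Nostrin (3.45, SE 0.58) and Zim1 (3.39, SE 0.45) were higher in KD1, and Lefty1 (-3.14, SE 0.55), Fndc3c1 (-2.24, SE 0.38) and Aqp3 (-1.46, SE 0.26) lower. Without the 2 displaced arrays, which leaves KD2 with 1 array per state, 437 and 742 genes differed (1585 and 1922 with the block). Acta2 (-2.91), Cdh2 (-2.23) and Tagln (-2.15) were then lower in KD1 in ESC, and in RA Ptk6 (3.37), Pga5 (3.21) and Isx (3.03) were higher and Lefty1 (-2.53) lower.

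**Figure D4:**
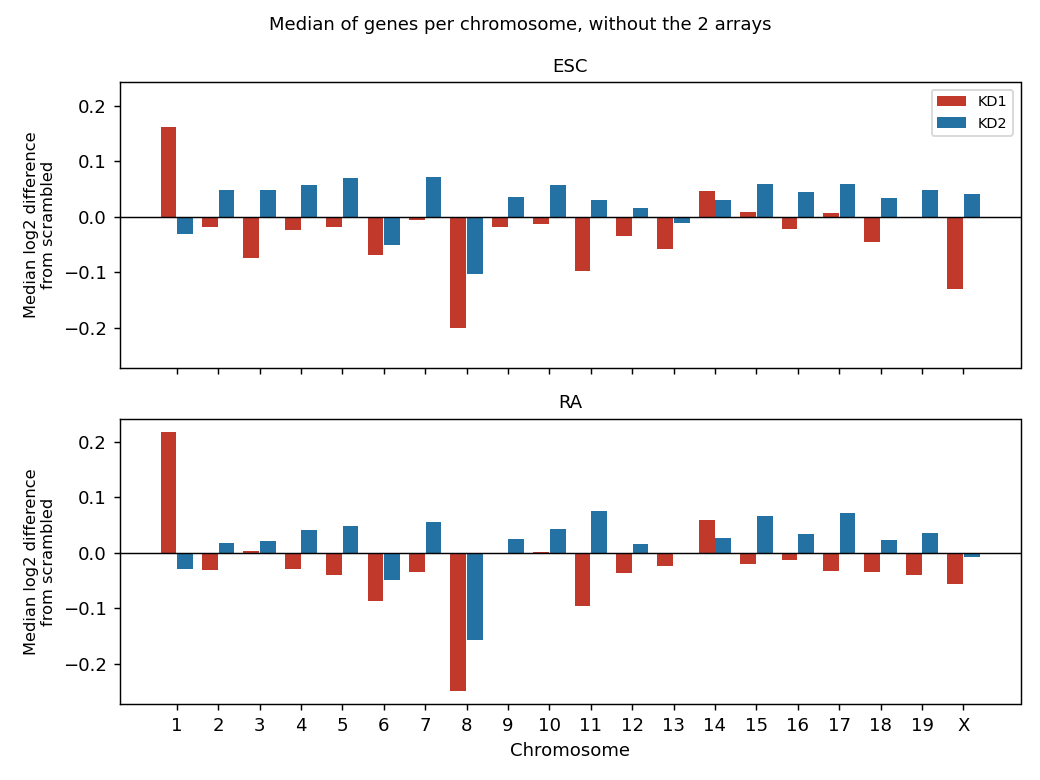
Median difference from scrambled of the genes of each chromosome, in KD1 and KD2, without the 2 displaced arrays.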

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

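The tests chosen only after the result was seen were those of mislabelled and of mixed samples, of copy number and of loss of SET for the chromosome shifts, of copy number (its allowance for spread) and of loss of SET for the endoderm genes, of chromosomes 1 and 14 and of KD1 alone for the same genes, and the counts over other splits of the arrays.

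The array labelled ESC KD2 replicate 2 and the array labelled RA KD2 replicate 2 stood far from their groups. On an axis over 739 genes called between RA and ESC in scrambled cells, with ESC KD2 replicate 1 at 0 and RA KD2 replicate 1 at 1, their median positions were 0.946 and -0.0025. Mixed RNA would need intermediate positions for each, and -0.0025 for the second argues against it; arrays from another line would lack KD2's own marks, yet over 9 such genes the lower of their positions was 0.757. Differentiation in stem cell medium without retinoic acid would leave retinoic acid and Hox genes low in the first array, but 8 called members stood at 0.936. Exchanged state labels within KD2 remain open and are consistent with 0.946 and its counterpart, found and tested on the same data; the design names no biological difference that was tested for it.

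The same displacement shaped the comparison of RA with ESC in knockdown cells. With the lines pooled, the real grouping of 8 knockdown arrays called 0 genes by limma (2386 at an unadjusted p below 0.05). All 35 splits into 4 and 4 give at least 0 by construction, so that count says nothing about chance. The highest other split called 8877 genes, which only restates the displacement, since that split exchanged the 2 displaced arrays. Without them the real grouping called 7744 genes, 1 of the 10 splits gave as many, and the highest other split called 0; 10 splits are too few for a share under 0.05.

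Genes of chromosome 1 were higher in KD1. Without the 2 displaced arrays their median against scrambled was 0.16 in ESC and 0.22 in RA, the highest of all autosomes, with 79.6% and 76.5% of 656 genes above 0. The values argue against loss of SET as the cause, since the KD2 median was at most -0.135 of that in KD1, and against an intensity-dependent error of the authors' normalization, since matching on expression left at least 1.005 of the difference. A gain of chromosome 1 copies in the KD1 line or a part of its cells remains open and is consistent with the lower of the medians, 0.162. DNA was not measured, and the design gives no biological group apart from the line.

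With all 12 arrays, 1 of the 29 endoderm list members off chromosomes 1 and 14 was called higher in RA. Without the 2 displaced arrays, endoderm genes were higher in the knockdown lines in RA, and mostly in KD1. Extra copies of chromosomes 1 and 14 raising only the genes on them are argued against for the 29 members elsewhere, of which 15 rose. How much of the list's median came from extra copies of the 4 members on these chromosomes cannot be told apart: without them it went from 1.17 to 0.58, a ratio of 0.492, just under the 0.5 first set as the bound, but 0.2 to 1 on resampling, which was added after that ratio was seen; effects of extra copies on genes elsewhere were not tested. Fewer cells of the main type would raise other lineages alike. In KD1 fibroblast genes stood at -0.182 (-0.39 to -0.13), trophoblast genes at -0.30 (-0.57 to -0.02) and endoderm genes at 1.87 (0.59 to 2.14). Fibroblast and trophoblast genes were also higher in RA than in ESC in scrambled cells and may mark the main type, so their fall does not decide. For the mean of the lines the lowest median, -0.094, does not decide either. Loss of SET may raise these genes, as the lowest of the 4 line medians was 0.22 (with all 12 arrays KD2 in RA had -0.20, and 15 of 33 above 0), but each knockdown is 1 line and a run of neighbouring genes was lower in both lines, so line and knockdown cannot be told apart.

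A difference between states or lines singled out further genes, for which no explanation was tested. Mamdc2 responded differently to the knockdown in the 2 states (-2.29). Between KD1 and KD2 in ESC the differences were 2.35 for Serpinb6c, 2.14 for Atp2a3, 2.04 for Slc13a5, 1.57 for Lrch1, 1.54 for Spata31d1a, -2.08 for Ghr, -2.03 for Krt18, -1.84 for Thbs1, -1.64 for Slc40a1 and -1.45 for Sema3e. With a replicate block within each state 0 of the ESC differences were called by limma (4229 genes at an unadjusted p below 0.05), and in RA Nostrin, Lefty1, Aqp3 and Cox7a1 (adjusted p = 0.0553) were not. In RA the differences were 3.61 for Ptk6, 3.50 for Klb, 3.45 for Nostrin, 3.45 for Cemip, 3.39 for Zim1, -3.14 for Lefty1, -2.24 for Fndc3c1, -2.02 for Cyp2b23, -1.65 for Cox7a1 and -1.46 for Aqp3.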

How the results depend on the processing

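The tests without the 2 displaced arrays and the block within each state were chosen only after the result was seen; the other alternatives were planned. Of 379 results for named genes 177 were called in the planned fit. Median centring kept 371 of the 379 on the same side of the threshold, the mean of probe sets 378, robust moderation 370, renewed quantile normalization 366, cyclic loess 360 and no trend 348. The replicate block over both states kept 258 and lost 120, only the groups compared kept 222, lost 66 and newly called 45, and leaving out 1 array at a time kept 1482, lost 678 and newly called 70. Pooled lines lost 31, line as a random block 29, KD1 alone 11 (21 newly called) and KD2 alone 33 (1 newly called). Without the 2 displaced arrays 177 stayed on their side, 201 became called and 1 reversed: Cyp26a1, KD against scrambled in RA, at 0.82. Of 135 list tests 77 were called; 76 were lost with an estimated correlation, 61 with fry and 1 with the replicate block. Without the 2 displaced arrays 10 list calls were lost, 7 lists became called and 2 reversed, ribosome biogenesis in KD against scrambled in ESC (adjusted p = 0.336) and epithelial junctions in RA against ESC in KD (adjusted p = 0.958).

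Counts below are higher and lower for main comparisons; the cause was not tested except where fewer arrays or genes enter. KD against scrambled in ESC (0 and 19) gave 107 and 100 without the 2 displaced arrays, 3 lower without dim genes, 2 lower with only the groups compared, 4 higher and 9 lower in KD1 alone and 2 higher in KD2 alone. KD against scrambled in RA (106 and 121) gave 532 and 674, then 66 and 38 without dim genes, 6 and 5 with only the groups compared, 8 and 68 with lines pooled, 12 higher with line as a random block, 315 higher in KD1 alone, 5 and 49 in KD2 alone and 78 lower with the replicate block. RA against ESC in scrambled cells (1622 and 1129) gave 4342 and 4154, then 3825 and 3520 with only the groups compared, and 176 and 62 with the block. RA against ESC in KD (100 and 5) gave 4258 and 3958, then 4 and 0 with only the groups compared, 0 and 0 with lines pooled, with line as a random block and in KD2 alone, 1400 and 849 in KD1 alone, 60 higher with the block and 8 lower with no trend. The interaction (1 and 5) gave 140 and 236, then 0 and 0 with no trend and without dim genes, 0 and 3 with robust moderation, every probe set, quantile normalization and cyclic loess, 41 and 11 in KD1 alone, and 0 higher in KD2 alone, with the block, with lines pooled and with line as a random block.

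Genes called in KD1 in ESC (13) became 383 without the 2 displaced arrays, 30 with no trend, 3 without dim genes and 6 with the block; in KD2 in ESC (17) they became 197, 9, 1 and 8, and 0 with only the groups compared. In KD1 in RA (463) they became 2407, and 3646 with only the groups compared; in KD2 in RA (54) 192, 32 with no trend, 0 without dim genes, 0 with only the groups compared and 12 with the block. KD1 against KD2 in ESC (26) became 437, 40 without dim genes, 5 with quantile normalization, and 0 with cyclic loess, only the groups compared and the block; in RA (268) it became 742, and 0 with only the groups compared. Each count of 0 is of limma. Leaving out 1 array at a time, the lone array left being assumed to vary like the other groups, gave these ranges, higher then lower: KD against scrambled in ESC 0 to 0 and 3 to 13, in RA 3 to 205 and 10 to 372; RA against ESC in scrambled 3 to 54 and 0 to 10, in KD 2 to 1742 and 0 to 1569; interaction 0 to 24 and 0 to 49. In the fit of 10 arrays they were, in the same order, 35 to 173 and 49 to 252, 205 to 274 and 237 to 397, 3316 to 4238 and 2968 to 3871, 3689 to 4118 and 3294 to 3689, and 41 to 267 and 74 to 283. For genes called in single lines with 12 arrays the ranges were 0 to 7 (KD1, ESC), 3 to 15 (KD2, ESC), 78 to 119 (KD1, RA), 5 to 1018 (KD2, RA), 0 to 0 (KD1 against KD2, ESC) and 30 to 1254 (RA).

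The replicate number as 1 block over both states is given here only, since replicate differences did not correlate throughout between states. In the fit of 10 arrays it gave 135 and 131 for KD against scrambled in ESC, 668 and 861 in RA, 4570 and 4394 for RA against ESC in scrambled, 4489 and 4167 in KD and 221 and 327 for the interaction, which gave 92 and 132 without dim genes in that fit. A replicate block within each state kept 174 results for named genes on their side, 28 were lost and 3 became called (Hoxd8, P4ha1 and Wars in RA). Of list tests 78 were kept, stress response in ESC (adjusted p = 0.0757) and mesoderm in the interaction (adjusted p = 0.0587) were lost and two-cell-stage genes in RA became called (adjusted p = 0.0383). With 10 arrays it lost 0 named results and newly called 16, Cldn4, Zic5, Mcm3, Myc and Cdc6 among them, and 7 list tests changed. KD against scrambled gave 0 and 7 in ESC and 103 and 120 in RA with it, and 688 and 536, and 1427 and 1886, with 10 arrays. Single lines gave 3 (KD1, ESC), 2 (KD2, ESC), 533 (KD1, RA) and 38 (KD2, RA). The line block had a correlation of -0.0825. Array number limits precision. Without dim genes 303 results for named genes stayed on their side, 20 became called and 6 were lost.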

Other observations

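The test of a lost stretch of the Y chromosome was chosen only after the result was seen, as were the scans of chromosomes and neighbouring genes.

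Kdm5d was lower in every knockdown array than in every scrambled array: the highest of 8 knockdown arrays read 5.85 and the lowest of 4 scrambled arrays 7.48. For a loss of a stretch of the Y chromosome in the knockdown lines, the arrays were compared within each state, without the 2 displaced arrays. All 3 measured genes from Zfy1 to Kdm5d were then lower in every knockdown array in both states, and 0 of the 6 measured Y genes outside were. Uba1y, between the others, still read up to 9.18 in a knockdown array. Outside the stretch, Eif2s3y, Uty and Zfy2 were lower in every knockdown array in 1 state each. The bounds of the stretch were set by Zfy1 and Kdm5d, which had already been called lower. Whether the stretch was lost or its genes were less expressed cannot be told apart, since DNA was not measured and each knockdown is 1 line.

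Runs of 15 neighbouring genes were scanned over 11554 windows in the fit without the 2 displaced arrays, added after the data were seen. On chromosome 14 the run from Lcp1 to Dnajc15 had medians of 0.88 in ESC and 1.17 in RA in KD1, against -0.01 and 0.00 in KD2, where shuffled gene orders reached 0.233. Zc3h13 (1.02 and 1.37), Cog3 (1.05 and 1.32) and Gpalpp1 (1.05 and 1.28) were among its genes, as KD1 values in ESC and RA. On chromosome 5 the run from Lap3 to Tbc1d19 was lower in both lines, by medians of -0.89 and -0.77 in KD1 and -0.68 and -0.81 in KD2 in ESC and RA, where shuffled orders reached -0.155. Lcorl (-1.13 and -0.94), Zcchc4 (-1.04 and -1.09) and Anapc4 (-0.98 and -1.05) were among its genes, again as KD1 values. Genes of chromosome 8 had medians of -0.20 and -0.25 in KD1 and -0.10 and -0.16 in KD2 in ESC and RA. These were the lowest of the chromosomes scanned. Other genes had medians of -0.02 and -0.02 in KD1 and 0.04 and 0.03 in KD2. Both lines were set against the same scrambled line. For chromosomes 5 and 8, a trait of that line therefore cannot be told apart from one of the knockdown lines.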
